A study of Homo sapiens with 11 samples.

How the data were processed

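The samples were 11 arrays of human mesenchymal stem cells in 4 groups, assigned from the labels: 3 TCM arrays, 3 5-Aza arrays, 3 DMEM arrays and 2 MEM arrays. Total RNA was extracted with an RNeasy kit and labelled with biotin for hybridisation, per the labels' protocols. The values were intensity signals of 54675 probe sets on a linear scale, deposited by the authors and made with MAS5 (Affymetrix's summary of the probes of a probe set), per the submitters' processing notes. The version and settings of MAS5 are not given in the sources used here. All values were above 0, and the mean after leaving out the lowest and highest 2% was between 150.019 and 150.021 on each array, so the arrays had been scaled to a common mean and were used without further normalization. Scanner files and detection calls were not used here, so signals of low probe sets are not separated from background. Every column of values in the table belonged to 1 of the 11 samples.

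Probe sets were named from the platform annotation. Of all probe sets, 62 were array controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Gene IDs of 41037 probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCh38.p14, which was used for names only and changed 0 symbols. These probe sets covered 19775 genes. Each gene was represented by the probe set with the highest mean signal, and genes were tested if that mean was above the 40th percentile of all probe sets, a signal of 22.9, which left 14251 genes. For the fixed genes and those with the largest changes, 78 pairs of gene and comparison had further probe sets above this signal. In 17 of them at least 1 had the opposite sign, and in 26 others the weakest was under 0.5 of the printed value, so a log2 fold change is that of 1 probe set. Values of such probe sets are given for some genes only, and averages over the probe sets of a gene include those below this signal. No coordinates are given because no genome was used.

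Signals were analysed as log2(signal + 32), so a fold change is on that scale and understates the change of genes with low signals. A linear model with 1 coefficient per group was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3, followed by empirical Bayes moderation with an intensity trend (prior degrees of freedom 7.74, residual degrees of freedom 7). All groups shared 1 estimate of the spread because the smallest group had 2 arrays. The 6 comparisons of the 4 groups were tested with limma's two-sided moderated test, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p below 0.05. The labels do not say whether replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. The labels used here give no batch or date, and the number of arrays limits the precision of the values.

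The 27 gene lists, the comparisons, their tests of genes and of lists, the rule for naming genes and all alternatives but 2 were fixed before the data were examined. The comparisons of marker genes with all genes and of lists with their nearest neighbours in signal, and the correlations with separate arrays of a shared control, were chosen after results were seen. The lists covered fibroblast and contractile markers, matrix, proteases, inflammatory and growth factor genes, TGF-beta, interferon, p53, hypoxia, cholesterol, fatty acid, amino acid, chaperone and NRF2 responses, replication, germline, imprinted and DNA methylation genes, lineage and stromal surface genes, and markers of blood-lineage, epithelial and endothelial cells. Each list was tested with camera in limma, which compares the members with all other genes, with an inter-gene correlation preset at 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The test was repeated with an estimated correlation. Of the 162 pairs of list and comparison 58 were called, and 14 were called with an estimated correlation. Lists overlap in some genes, so their results are not independent.

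Named genes had to be called and to have no overlap between the arrays of both groups. They were the 10 with the largest increase and the 10 with the largest decrease in TCM against DMEM, 5-Aza against MEM and 5-Aza against DMEM, and the 5 and 5 in the other comparisons. Up to 4 members of a list per comparison, those with the smallest adjusted p, could also be named. ACTA2, VIM, S100A4, FAP, CXCL12, TNC, THBS1, FN1, PDGFRB and DNMT1 are given in both exposures whatever their result. Genes of chromosome Y and of X inactivation, polymorphic genes of the major histocompatibility complex, genes commonly deleted in people, immunoglobulin genes, and probe sets with several or no symbols were left out of the named genes.

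The fit was tested on simulated data with 200 changed genes among 14251. At log2 changes of 0.5, 1 and 2 it recovered 66.7%, 95.5% and 100% of the changed genes for TCM against DMEM. The shares were 56.1%, 95.5% and 100% for 5-Aza against DMEM, 65.2%, 97% and 100% for 5-Aza against MEM, and 51.5%, 86.6% and 100% for DMEM against MEM. Of the genes called, 7 of 182, 7 of 175, 10 of 185 and 10 of 169 had not been changed. A list shifted by 0.3 in TCM was tested in 1 further simulation, for TCM against DMEM alone. That list was called and 0 other lists were. Genes varied independently of each other in these simulations, with the moderated spread of the fit as their true spread. More genes were called in the measured data, 773 to 3978 per comparison, so the shares recovered need not hold there. For comparisons that share control arrays, unchanged groups were simulated 100 times with the moderated spread of each gene.

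The alternatives were quantile normalization, centring of each array on its median, pseudocounts of 1 and 128, no filter or a filter at the 60th percentile, the mean over all probe sets of a gene, no intensity trend, array weights, only the arrays of the groups compared, the replicate number as a block, and each array left out in turn. With 1 MEM array left out, the remaining one was assumed to vary like the arrays of the other groups. A fit without the MEM group, and the count of shared genes without an intensity trend, were added after the data were seen.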

Results

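Gene expression was measured with Affymetrix arrays in total RNA of human mesenchymal stem cells (hMSCs), stromal cells from bone marrow that can form bone, cartilage and fat. The stated purpose was to follow differentiation of these cells under tumour-conditioned medium or an epigenetic modifier, and the series title names a carcinoma-associated fibroblast state. The 11 arrays fell into 4 groups. In the first group, called TCM here, cells were kept for 30 days in 100% medium conditioned by MDA-MB-231 cells, an established line of breast carcinoma cells (n = 3). In the group called 5-Aza, cells were exposed to 5-azacytidine, a cytidine analogue that inhibits DNA methyltransferases, and cultured for 21 days (n = 3). The controls were cells kept for 30 days in DMEM (n = 3) or in alpha MEM (n = 2, called MEM), which are both standard culture media, and medium was changed every 3 days in all groups. The labels used here do not name the base medium of the 5-Aza cultures, so each exposure was compared with both controls. The labels also give neither the dose nor the length of the 5-azacytidine exposure. The 5-Aza cells also differed from the controls in days of culture.

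Each array gave a signal for 54675 probe sets, and 14251 genes were tested. The median signal of an array lay between 32.8 and 39.1 and the highest signal between 10890 and 13320. The ratio of 3' to 5' control probe sets was 0.963 to 1.01 for GAPDH and 1.11 to 1.30 for ACTB, with the lowest ACTB ratios, 1.16 and 1.11, on the MEM arrays. Correlations across genes were 0.988 to 0.991 between arrays of a group, 0.982 to 0.986 between TCM, 5-Aza and DMEM arrays, and 0.963 to 0.971 between MEM and all other arrays. The first principal component held 37% of the variance and set both MEM arrays, at 35.9 and 34.7, apart from the other arrays, which lay between -14.0 and -3.88. On the second component, with 14% of the variance, the TCM arrays lay between 11.5 and 14.9 and the DMEM arrays between -16.2 and -11.0, with the 5-Aza arrays between them. The third component, with 11% of the variance, set the 5-Aza arrays, at -17.7 to -9.88, apart from all others, at 0.08 to 10.9. The small number of arrays limits the precision of every value below. Log2 fold changes are given ± SE and signals as mean ± SD over the arrays of a group, and p-values are adjusted.

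**Figure D1:**
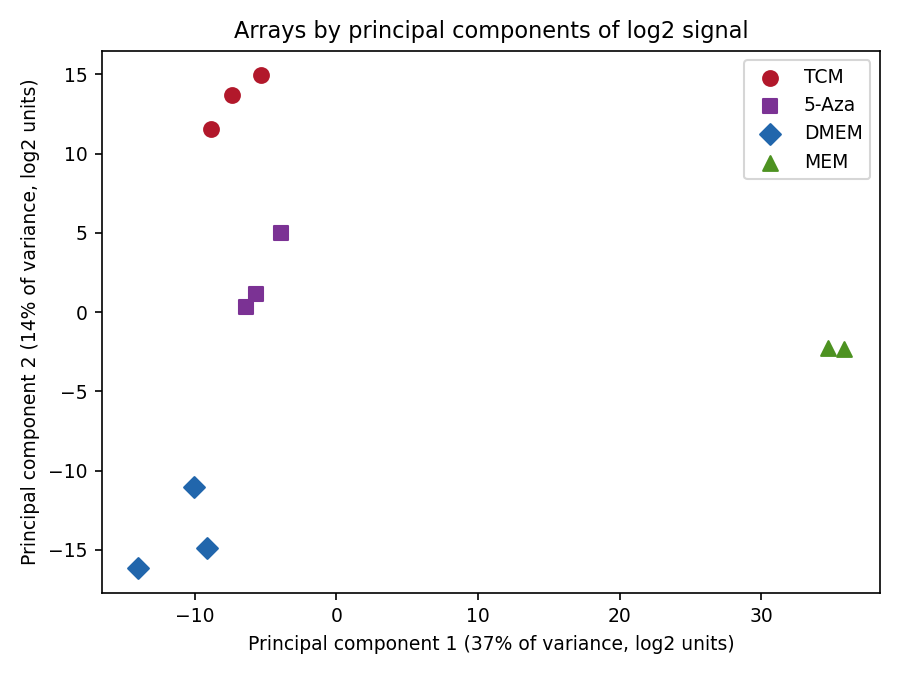
Each point is 1 of the 11 arrays, placed by the first principal component of log2 signal (horizontal, 37% of the variance) and the second (vertical, 14%), in log2 units, with colour and shape for the group. Both MEM arrays lie at 34.7 or above on the first component, and the TCM and DMEM arrays lie at opposite ends of the second.

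The controls themselves differed. All 38 tested genes of DNA replication and mitosis were lower in DMEM than in alpha MEM, while 21 of 34 genes of the hypoxia response and glycolysis, 19 of 34 secreted growth factors and 15 of 39 matrix genes were higher in DMEM. RRM2, a subunit of ribonucleotide reductase, gave a signal of 27.9 ± 13.3 in DMEM and 789.8 ± 164 in alpha MEM, a log2 fold change of -3.79 ± 0.17 (adjusted p = 7.84e-10). TOP2A, a DNA topoisomerase of dividing cells, gave 18.7 ± 3.28 and 387 ± 71.8 (log2 fold change -3.04 ± 0.14). The DMEM signals of both genes lay near the signal of 22.9 that genes had to exceed on average to be tested. The sizes of their changes against DMEM, here and below, are therefore uncertain. COL15A1, a collagen of basement membrane zones, gave 933 ± 88.1 in DMEM and 55.1 ± 5.01 in alpha MEM (log2 fold change 3.47 ± 0.07, adjusted p = 2.42e-13). In total 1933 genes were higher and 2045 lower in DMEM, or 2377 higher and 1483 lower when each array was centred on its median.

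The other genes with the largest increases in DMEM over alpha MEM were EPYC, a small proteoglycan of cartilage (log2 fold change 3.62 ± 0.19), MXRA5, a matrix-remodelling associated protein (3.16 ± 0.12), IGF1, insulin-like growth factor 1 (2.95 ± 0.15), and VCAM1, an adhesion molecule for leukocytes (2.90 ± 0.08). The other genes with the largest decreases were BEX1 (-4.11 ± 0.12), LYPD1 (-3.09 ± 0.20) and PCLAF, a PCNA-associated factor (-3.01 ± 0.15, and -0.93 for another probe set). All 38 tested genes of DNA replication and mitosis fell, both over all genes and adjusted over the list alone, with a median log2 fold change of -1.47 (adjusted p = 5.02e-27). The list was called as well at adjusted p = 0.0301 with an estimated correlation. Of 34 hypoxia-response and glycolysis genes, 21 rose and none fell, with 25 higher adjusted over the list alone (adjusted p = 2.60e-16; adjusted p = 0.042 with an estimated correlation). They included ENO2, the neuronal enolase (2.23 ± 0.10), the mitophagy receptor gene BNIP3 (1.39 ± 0.07) and P4HA1, a collagen prolyl hydroxylase subunit (1.14 ± 0.06).

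Of 31 genes of the amino acid deprivation response, targets of the transcription factor ATF4, 25 were lower and 2 higher in DMEM than in alpha MEM, with the same numbers adjusted over the list alone (adjusted p = 4.31e-14; adjusted p = 0.0301 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, was at 891 ± 22.6 in DMEM and 1819 ± 52.8 in alpha MEM. PSPH, the last enzyme of serine synthesis, had a log2 fold change of -1.44 ± 0.07. Secreted growth factors rose in 19 and fell in 7 of 34 members, also adjusted over the list alone (adjusted p = 0.000136; adjusted p = 0.0301 with an estimated correlation). Inflammatory genes rose in 11 and fell in 2 of 25, also adjusted over the list alone (adjusted p = 0.00301; adjusted p = 0.042 with an estimated correlation). Extracellular matrix genes rose in 15 and fell in 4 of 39 members, also adjusted over the list alone (adjusted p = 0.000165). This call was lost, at adjusted p = 0.413 with an estimated correlation. It was lost too for matrix proteases and inhibitors (9 higher and 1 lower of 20; adjusted p = 0.000538; adjusted p = 0.213 with an estimated correlation). It was also lost for endoplasmic reticulum chaperones (10 higher and 1 lower of 22; adjusted p = 0.00178; adjusted p = 0.136 with an estimated correlation). Transforming growth factor beta (TGF-beta) response genes rose in 10 and fell in 6 of 26 (adjusted p = 0.0182; adjusted p = 0.198 with an estimated correlation). Oxidative stress genes, targets of NRF2, fell in 8 and rose in 4 of 16 (adjusted p = 0.0251; adjusted p = 0.121 with an estimated correlation). Adjusted over the list alone, these 4 lists had 11 higher and 1 lower, 11 higher and 2 lower, 11 higher and 6 lower, and 4 higher and 11 lower members. The TGF-beta and NRF2 lists were no longer called when probe sets of a gene were averaged, nor the TGF-beta list with a filter at the 60th percentile. NQO1, a quinone reductase under NRF2, was at 552 ± 29.2 in DMEM and 2607 ± 20.6 in alpha MEM (log2 fold change -2.18 ± 0.06).

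Cells under tumour-conditioned medium were first compared with cells in DMEM. COL15A1 rose from 933 ± 88.1 to 4380 ± 152, a log2 fold change of 2.20 ± 0.07 (adjusted p = 3.74e-11), and ENPP2, which encodes the lysophospholipase autotaxin, rose from 206 ± 9.44 to 916 ± 106 (1.99 ± 0.09, adjusted p = 3.83e-09). Of 19 smooth muscle contractile genes 9 fell, and the call of the list was lost with an estimated correlation (adjusted p = 5.09e-11; adjusted p = 0.064 with an estimated correlation). CNN1, the smooth muscle calponin, went from 2351 ± 158 to 846 ± 127 (-1.45 ± 0.10, adjusted p = 3.53e-07) and SYNPO2, an actin-bundling protein, from 3273 ± 162 to 1247 ± 104 (-1.37 ± 0.06, adjusted p = 3.83e-09). Of 31 genes of the amino acid deprivation response 21 rose. S100A4, a calcium-binding protein used as a fibroblast marker, rose from 113 ± 3.12 to 253 ± 26.7 (0.97 ± 0.10, adjusted p = 1.46e-05).

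In total 713 genes were higher and 772 lower in TCM than in DMEM, of which 19 and 39 changed by 2-fold or more. With each array centred on its median the split was 458 higher and 892 lower, and without an intensity trend in the variance 983 genes were called in place of 1485. After COL15A1 and ENPP2, the largest increases were those of the urea transporter SLC14A1 (1.87 ± 0.11), PLPPR4 (1.69 ± 0.13), the ubiquitin ligase RNF128 (1.53 ± 0.11), FOS, an immediate-early transcription factor (1.50 ± 0.14), the calcium-activated chloride channel ANO1 (1.49 ± 0.11), and RSPO3, an enhancer of Wnt signalling (1.43 ± 0.12). GAS7 (1.35 ± 0.14) and the nucleoside transporter SLC29A1 (1.25 ± 0.11) completed the 10 largest. Other probe sets gave 0.465 for ANO1 and 0.65 to 1.095 for GAS7. The largest decreases were those of THEMIS (-1.94 ± 0.14), the cardiac actin ACTC1 (-1.91 ± 0.15), the death receptor TNFRSF21 (-1.80 ± 0.31), the serpin SERPINB7 (-1.64 ± 0.13), the oxytocin receptor OXTR (-1.64 ± 0.10), and the ephrin receptor EPHA5 (-1.54 ± 0.13). They were followed by GREM1 and NOG, both antagonists of bone morphogenetic proteins (-1.52 ± 0.11 and -1.501 ± 0.17), the embryonic myosin MYH3 (-1.501 ± 0.25) and ID2, an inhibitor of DNA binding (-1.46 ± 0.07). The TCM signals of THEMIS, TNFRSF21 and EPHA5, 24.5 ± 8.56, 24.5 ± 18.1 and 21.1 ± 3.85, lay close to the signal of 22.9 that genes had to exceed on average to be tested. Another TNFRSF21 probe set gave -0.63. The DMEM signals of PLPPR4 and RNF128, 31.4 and 35.5, and the TCM signal of NOG, 33.8, were also low. The sizes of these changes are therefore uncertain.

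Of 31 tested genes of the amino acid deprivation response, 21 rose and none fell in TCM against DMEM, with 24 higher adjusted over the list alone (adjusted p = 2.60e-16). This was the single list of this comparison that was also called with an estimated correlation (adjusted p = 0.0242 with an estimated correlation). TRIB3 rose by 0.65 ± 0.05, WARS1, the tryptophanyl-tRNA synthetase, by 0.57 ± 0.05, ASNS, asparagine synthetase, by 0.56 ± 0.05 and PHGDH, the first enzyme of serine synthesis, by 0.62 ± 0.06. These genes were lower in DMEM than in alpha MEM, as given above. Of the contractile genes none rose, and 12 were lower adjusted over the list alone. Besides CNN1 and SYNPO2 these included MYOCD, the coactivator myocardin (-0.83 ± 0.11), and LMOD1, leiomodin (-0.75 ± 0.11). TGF-beta response genes fell in 10 and rose in 1 of 26 members, with 13 lower and 3 higher adjusted over the list alone (adjusted p = 2.16e-06; adjusted p = 0.0512 with an estimated correlation). The members with the smallest p were ID2, ID1 (-1.10 ± 0.09) and ID3 (-0.67 ± 0.07), which bone morphogenetic proteins also induce, and IGFBP5 (-0.42 ± 0.06).

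Hypoxia-response and glycolysis genes fell in 8 and rose in 1 of 34 members in TCM against DMEM, with 13 lower and 1 higher adjusted over the list alone (adjusted p = 5.01e-06; adjusted p = 0.263 with an estimated correlation), among them NDRG1 (-0.72 ± 0.06) and ANKRD37 (-0.76 ± 0.07). Secreted growth factors fell in 10 and rose in 3 of 34, with 13 lower and 7 higher adjusted over the list alone (adjusted p = 0.0102; adjusted p = 0.0864 with an estimated correlation). HBEGF, an epidermal growth factor receptor ligand, rose by 0.74 ± 0.08, and STC1, the hormone stanniocalcin, had a log2 fold change of -0.90 ± 0.10. Genes of DNA replication and mitosis rose in 9 of 38 members and fell in none, with 11 higher adjusted over the list alone (adjusted p = 1.31e-05; adjusted p = 0.263 with an estimated correlation). Signals in TCM were 51.5 ± 7.95 for TOP2A (0.72 ± 0.13), a change that was not called at 0.33 when its probe sets were averaged, and 519 ± 66.2 for MCM6 (0.46 ± 0.09). Of 25 p53 target and cell-cycle arrest genes, 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.00131; adjusted p = 0.064 with an estimated correlation), led by the stress cytokine GDF15 (0.72 ± 0.05). Extracellular matrix genes fell in 6 and rose in 5 of 39, with 10 lower and 5 higher adjusted over the list alone (adjusted p = 0.0128; adjusted p = 0.544 with an estimated correlation). Their shift, the mean log2 fold change of the members minus that of all other genes, was -0.06 and was no longer called without TCM replicate 1 (-0.04), without DMEM replicate 1 (-0.04) or after quantile normalization (0.01). Cholesterol synthesis genes fell in 2 of 17, also adjusted over the list alone (adjusted p = 0.000783; adjusted p = 0.064 with an estimated correlation). Interferon-stimulated genes shifted upward with 2 of 31 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.0168; adjusted p = 0.263 with an estimated correlation), a shift of 0.15 that was not called without TCM replicate 1 (0.13) or DMEM replicate 2 (0.13). The inflammatory list was not called (adjusted p = 0.232), although VCAM1 rose by 1.10 ± 0.07 and CCL2, a monocyte chemokine, by 1.15 ± 0.12, while PTGS2, cyclooxygenase 2, fell by 1.03 ± 0.13 on the log2 scale.

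The list of carcinoma-associated fibroblast and myofibroblast markers did not shift as a whole between TCM and DMEM (adjusted p = 0.0997). Of its 19 tested members 4 rose and 5 fell, or 5 and 8 adjusted over the list alone, and the list was called lower without DMEM replicate 3, at a shift of -0.13. Besides S100A4, TNC, the matrix glycoprotein tenascin C, rose by 0.42 ± 0.06 (adjusted p = 0.00039) and PDGFRB, a platelet-derived growth factor receptor, by 0.40 ± 0.09 (adjusted p = 0.00884). ACTA2, smooth muscle alpha actin and a myofibroblast marker, had a log2 fold change of -0.29 ± 0.07 (adjusted p = 0.0182) and the chemokine CXCL12 one of -0.30 ± 0.06 (adjusted p = 0.00535). The ACTA2 call was lost without TCM replicate 1 (-0.27) or 2 (-0.28), without DMEM replicate 1 (-0.24) or 2 (-0.28), without the signal filter and without an intensity trend, which also ended the PDGFRB call. No change was called for FAP, fibroblast activation protein (-0.15 ± 0.06, adjusted p = 0.0973), the intermediate filament gene VIM (-0.03 ± 0.07), the matrix genes FN1 (-0.10 ± 0.07) and THBS1 (-0.04 ± 0.08), or DNMT1, the maintenance DNA methyltransferase (0.08 ± 0.08). VIM, FN1, THBS1 and ACTA2 had mean signals of 7809 to 10400 in TCM, near the highest signals of an array, and a dimmer VIM probe set gave 0.38. The other TNC probe sets gave 0.05 to 0.46. Averaged over its probe sets, THBS1 was called lower (-0.28), and ACTA2 (-0.14) and CXCL12 (-0.18) were not called.

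**Figure D2:**
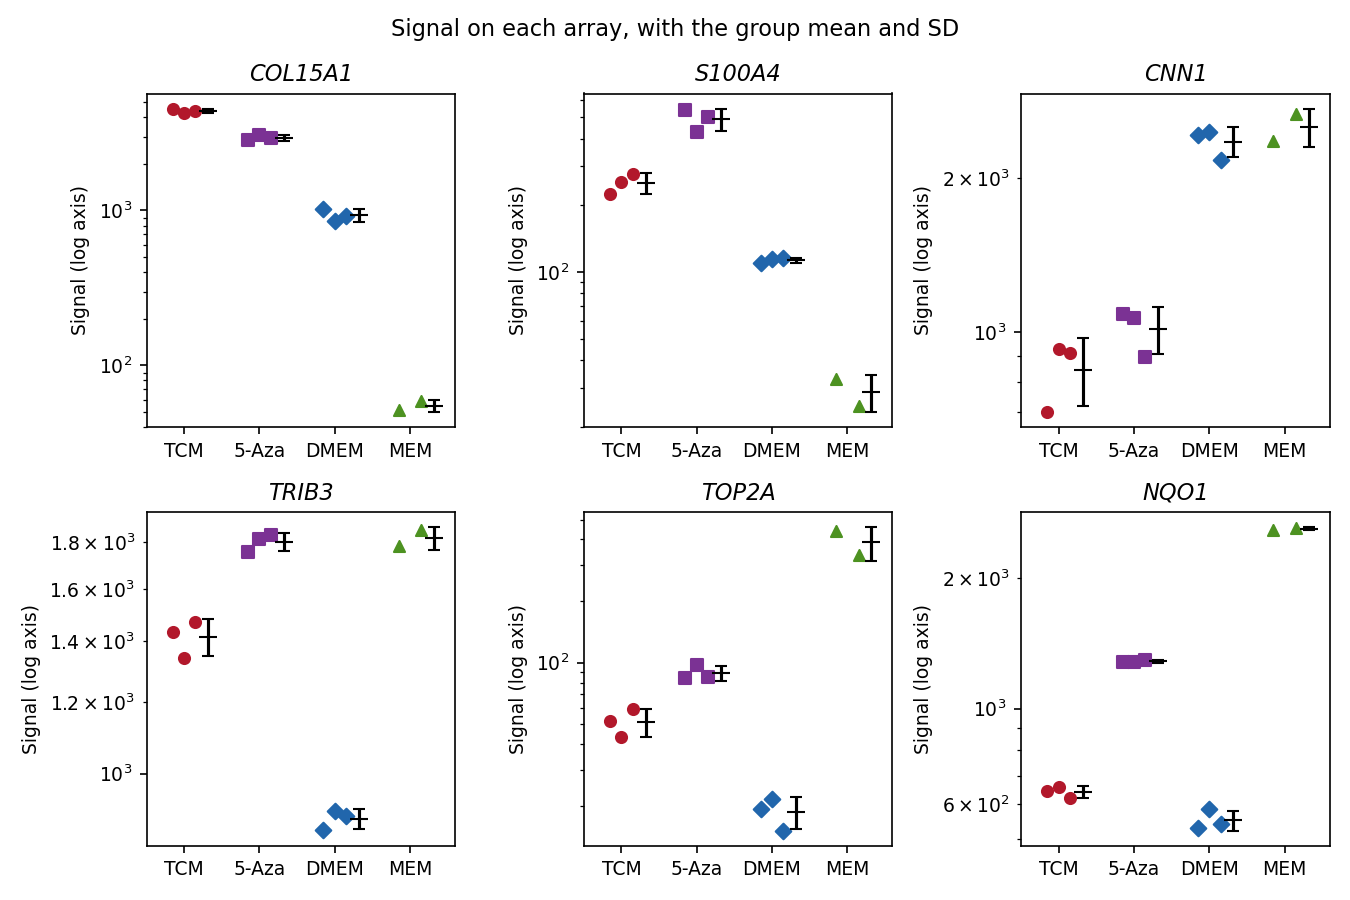
Each panel shows the signal of 1 gene on each array (log axis) by group, with a black bar for the group mean and whiskers of 1 SD. COL15A1 and S100A4 lie higher and CNN1 lower in TCM and 5-Aza than in DMEM, TRIB3 and TOP2A lie lowest in DMEM, and NQO1 is at 1286 in 5-Aza, 642 in TCM, 552 in DMEM and 2607 in MEM.

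Against alpha MEM, TCM cells differed in 3166 genes, 1618 higher and 1548 lower (1760 and 1299 with each array centred on its median). COL15A1 had a log2 fold change of 5.66 ± 0.07 (4380 ± 152 against 55.1 ± 5.01), VCAM1 one of 4.01 ± 0.08, MXRA5 3.40 ± 0.12, IGFBP2, an insulin-like growth factor binding protein, 3.36 ± 0.07, and CPE, carboxypeptidase E, 3.15 ± 0.09. The largest decreases were those of BEX1 (-4.48 ± 0.12), LYPD1 (-3.61 ± 0.20), RRM2 (-3.14 ± 0.17), PCLAF (-2.48 ± 0.15) and RGS5, a regulator of G-protein signalling found in pericytes (-2.46 ± 0.20, and -1.94 to -0.14 for its other probe sets). Contractile genes fell against this control as well, in 12 of 19 members with 1 higher, or 12 lower and 2 higher adjusted over the list alone (adjusted p = 2.88e-06; adjusted p = 0.101 with an estimated correlation). ACTG2, the smooth muscle gamma actin, was at -2.01 ± 0.08 and CNN1 at -1.54 ± 0.11.

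The directions of the replication, amino acid, hypoxia and growth factor lists in TCM depended on which control was used. The p53 and arrest list rose against both controls. The inflammatory, protease, chaperone and NRF2 lists were called against alpha MEM and not against DMEM. The TGF-beta, extracellular matrix, interferon and cholesterol lists were called against DMEM and not against alpha MEM (adjusted p = 0.747, 0.107, 0.521 and 0.997). Against alpha MEM the TGF-beta response genes rose in 7 and fell in 8 of 26 members, or 7 and 9 adjusted over the list alone. Replication and mitosis genes fell in 36 of 38 members against alpha MEM, or 37 adjusted over the list alone (adjusted p = 8.50e-27; adjusted p = 0.068 with an estimated correlation). Amino acid deprivation response genes fell in 13 and rose in 2 of 31, or 15 and 2 adjusted over the list alone (adjusted p = 9.40e-05; adjusted p = 0.101 with an estimated correlation). Hypoxia-response and glycolysis genes rose in 21 and fell in 1 of 34, or 25 and 1 adjusted over the list alone (adjusted p = 1.03e-12; adjusted p = 0.0788 with an estimated correlation). Secreted growth factors rose in 16 and fell in 6 of 34, or 16 and 7 adjusted over the list alone (adjusted p = 0.00735; adjusted p = 0.0788 with an estimated correlation). Inflammatory genes rose in 10 and fell in 2 of 25, or 10 and 3 adjusted over the list alone (adjusted p = 0.00276; adjusted p = 0.068 with an estimated correlation), with CCL2 at 2.09 ± 0.13. The p53 and arrest list rose in 13 and fell in 5 of 25, or 14 and 5 adjusted over the list alone (adjusted p = 0.00276; adjusted p = 0.0788 with an estimated correlation). The cell-cycle inhibitors CDKN2B and CDKN2A were at 1.27 ± 0.08 and 1.12 ± 0.07. Proteases and inhibitors rose in 8 and fell in 2 of 20, or 9 and 3 adjusted over the list alone (adjusted p = 0.0036; adjusted p = 0.339 with an estimated correlation). Endoplasmic reticulum chaperones rose in 7 of 22, also adjusted over the list alone (adjusted p = 0.0129; adjusted p = 0.223 with an estimated correlation). NRF2 targets fell in 8 and rose in 1 of 16, or 8 and 2 adjusted over the list alone (adjusted p = 0.00276; adjusted p = 0.068 with an estimated correlation). Among the fibroblast markers, S100A4 (2.23 ± 0.11), TNC (1.06 ± 0.07), PDGFRB (0.65 ± 0.10) and FAP (0.26 ± 0.06) were higher than in alpha MEM. ACTA2 (-0.50 ± 0.08), CXCL12 (-0.75 ± 0.07) and DNMT1 (-0.46 ± 0.09) were lower, while VIM (-0.06 ± 0.08), FN1 (-0.10 ± 0.08) and THBS1 (0.03 ± 0.09) were not called. The controls differed in the same directions. In DMEM against alpha MEM the log2 fold changes were 1.26 for S100A4, 0.64 for TNC, 0.25 for PDGFRB and 0.41 for FAP. They were -0.22 for ACTA2, -0.455 for CXCL12 and -0.54 for DNMT1, so values against alpha MEM include a difference between the media. S100A4 signals on the MEM arrays, 32.6 and 24.9, lay near the signal filter of 22.9. The sizes of its changes against alpha MEM, here and below, are therefore uncertain. FAP was not called without MEM replicate 2 (0.19). The second CXCL12 probe set gave -0.01, and 5 of the 6 dimmer THBS1 probe sets had negative values, down to -0.37. The dimmer FN1 probe sets gave -0.31 to 0.26, and the other TNC probe sets 0.264 to 0.645.

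Cells exposed to 5-azacytidine shared several leading genes with TCM cells when both were compared with DMEM. S100A4 rose from 113 ± 3.12 to 491 ± 56.1, a log2 fold change of 1.85 ± 0.10 (adjusted p = 3.19e-08), and COL15A1 from 933 ± 88.1 to 2949 ± 130.2 (1.63 ± 0.07, adjusted p = 2.21e-09). OXTR fell from 1638 ± 202 to 488 ± 15.8 (-1.68 ± 0.10, adjusted p = 4.60e-08) and SYNPO2 from 3273 ± 162 to 1213 ± 41.4 (-1.41 ± 0.06, adjusted p = 2.24e-09). NQO1 rose from 552 ± 29.2 to 1286 ± 8.53 (1.18 ± 0.05, adjusted p = 2.24e-09), and 25 of 31 genes of the amino acid deprivation response rose.

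In total 800 genes were higher and 637 lower in 5-Aza than in DMEM, 20 and 15 of them by 2-fold or more. With each array centred on its median the majority turned, with 580 higher and 680 lower, and without an intensity trend in the variance 947 genes were called in place of 1437. The other largest increases were those of FOS (1.65 ± 0.14), SLC14A1 (1.53 ± 0.11), ATF5, a transcription factor of the ATF4 pathway (1.38 ± 0.12), the kinase DCLK1 (1.30 ± 0.13), and the neutrophil chemokine CXCL2 (1.26 ± 0.17). They were followed by TOP2A (1.25 ± 0.13), the molybdenum cofactor sulfurase MOCOS (1.21 ± 0.07) and the retinaldehyde dehydrogenase ALDH1A3 (1.21 ± 0.11). The other largest decreases were those of EPHA5 (-1.38 ± 0.13), the membrane glycoprotein CD200 (-1.37 ± 0.13), NOX4, an NADPH oxidase induced by TGF-beta (-1.31 ± 0.12), and PKIB (-1.25 ± 0.11). They were followed by PPP1R14A, an inhibitor of smooth muscle myosin phosphatase (-1.25 ± 0.07), CSRP2, a LIM-domain protein of smooth muscle (-1.23 ± 0.05), CNN1 (-1.19 ± 0.10) and IGF1 (-1.07 ± 0.13). With its probe sets averaged, CXCL2 was not called (0.33). Other probe sets gave 0.52 to 1.50 for DCLK1, 0.60 for MOCOS, -0.58 for EPHA5 and -1.64 to -0.49 for SYNPO2.

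Amino acid deprivation response genes rose in 25 and fell in 1 of 31 members in 5-Aza against DMEM, or 26 and 1 adjusted over the list alone (adjusted p = 9.67e-25; adjusted p = 0.00341 with an estimated correlation). TRIB3 was at 0.99 ± 0.05 and SLC7A11, the cystine transporter, at 0.79 ± 0.05. NRF2 targets rose in 9 of 16 and fell in none, or 10 adjusted over the list alone (adjusted p = 1.56e-09; adjusted p = 0.00341 with an estimated correlation). These 2 lists, which share SLC7A11, were the ones also called with an estimated correlation in this comparison. The rise of the NRF2 list depended on the control. In 5-Aza against alpha MEM it was not called, with 4 members higher and 5 lower of 16 (adjusted p = 0.898). Contractile genes fell in 7 of 19 and rose in none, or 9 adjusted over the list alone (adjusted p = 1.99e-07; adjusted p = 0.145 with an estimated correlation). Replication and mitosis genes rose in 11 of 38 and fell in none, or 18 adjusted over the list alone (adjusted p = 1.63e-09; adjusted p = 0.148 with an estimated correlation), with RRM2 at 82.7 ± 2.18 in 5-Aza. TGF-beta response genes fell in 11 and rose in 3 of 26, or 11 and 4 adjusted over the list alone (adjusted p = 0.00555; adjusted p = 0.148 with an estimated correlation). The p53 and arrest list rose in 8 and fell in 2 of 25, or 8 and 3 adjusted over the list alone (adjusted p = 0.000558; adjusted p = 0.0729 with an estimated correlation), with GDF15 at 0.89 ± 0.05. Interferon-stimulated genes rose in 5 of 31, also adjusted over the list alone (adjusted p = 0.000751; adjusted p = 0.148 with an estimated correlation), led by the apoptosis factor XAF1 (0.76 ± 0.08). Surface markers of mesenchymal stromal cells rose in 5 and fell in 1 of 17, or 6 and 1 adjusted over the list alone (adjusted p = 0.00744; adjusted p = 0.32 with an estimated correlation). The hyaluronan receptor CD44 was at 0.57 ± 0.06 and the adhesion molecule MCAM at -0.87 ± 0.08 (-0.32 and not called with its probe sets averaged). The list was not called without DMEM replicate 3, at a shift of 0.10.

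The fibroblast marker list did not shift in 5-Aza against DMEM (3 of 19 higher and 3 lower, or 3 and 4 adjusted over the list alone, adjusted p = 0.903). Besides S100A4, ACTA2 had a log2 fold change of -0.30 ± 0.07 (adjusted p = 0.0147) and CXCL12 one of 0.25 ± 0.06 (adjusted p = 0.017), although its second probe set gave -0.09. The ACTA2 call was lost without 5-Aza replicate 2 (-0.25) or DMEM replicate 1 (-0.25). The CXCL12 call was lost without 5-Aza replicate 1 (0.24) or 2 (0.23) or DMEM replicate 1 (0.24) or 2 (0.24), and both calls were lost without an intensity trend. Averaging probe sets also ended the CXCL12 call (0.08). Values of 0.08 ± 0.06 for TNC, 0.18 ± 0.09 for PDGFRB, 0.05 ± 0.06 for FAP, 0.01 ± 0.07 for VIM, -0.04 ± 0.07 for FN1 and 0.01 ± 0.08 for THBS1 were not called, although PDGFRB was called without 5-Aza replicate 1 (0.29). The 6 dimmer THBS1 probe sets gave -1.02 to -0.21, the average over all its probe sets -0.34, and the dimmer VIM probe set 0.45, and averaged over its probe sets VIM was called higher (0.23). DNMT1, the enzyme that 5-azacytidine traps on DNA, was at 274 ± 11.8 in 5-Aza and 274 ± 20.1 in DMEM (adjusted p = 0.999). Of 34 germline and cancer-testis genes known to be silenced by DNA methylation, 24 were below the signal filter, and none of the 5 tested was called (adjusted p = 0.721 for the list). Without the filter, limma called 1 of 29 measured members higher in 5-Aza than in DMEM and none lower, with 1 higher at an unadjusted p under 0.05. It was DAZL, a germ cell RNA-binding protein (log2 fold change 0.60, adjusted p = 0.0391), named after its value was seen.

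Against alpha MEM, 5-Aza cells differed in 3241 genes, 1716 higher and 1525 lower (1959 and 1189 with each array centred on its median), a count that dropped to 2144 without MEM replicate 1 and to 2065 without MEM replicate 2. The largest increases were those of COL15A1 (5.10 ± 0.07), VCAM1 (3.21 ± 0.08), S100A4 (3.10 ± 0.11), IGFBP2 (3.00 ± 0.07), MXRA5 (2.85 ± 0.12), and EPYC (2.82 ± 0.19). They were followed by KRT14, a keratin of basal epithelium (2.71 ± 0.10), CPE (2.59 ± 0.09), CCND2, cyclin D2 (2.53 ± 0.10, and 0.33 to 1.26 for its other probe sets), and COMP, a cartilage matrix protein (2.51 ± 0.07). The largest decreases were those of BEX1 (-3.41 ± 0.12), RRM2 (-2.83 ± 0.17), LYPD1 (-2.37 ± 0.20), and the cyclin-dependent kinase CDK1 (-2.13 ± 0.15). They were followed by ZNF367 (-2.09 ± 0.18), PCLAF (-2.06 ± 0.15), OXTR (-1.97 ± 0.11) and RGS5 (-1.97 ± 0.20). The pregnancy-specific glycoprotein genes PSG3 (-1.93 ± 0.21) and PSG5 (-1.93 ± 0.11) belong to a family of near-identical genes whose probe sets may share targets, so their values are uncertain.

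Replication and mitosis genes fell in 35 of 38 members in 5-Aza against alpha MEM, or 36 adjusted over the list alone (adjusted p = 2.35e-24; adjusted p = 0.039 with an estimated correlation). Hypoxia-response and glycolysis genes rose in 26 and fell in 1 of 34, also adjusted over the list alone (adjusted p = 1.92e-18). Secreted growth factors rose in 20 and fell in 6 of 34, or 20 and 7 adjusted over the list alone (adjusted p = 0.00011). Inflammatory genes rose in 7 and fell in 1 of 25, or 7 and 2 adjusted over the list alone (adjusted p = 0.00232). The p53 and arrest genes rose in 14 and fell in 3 of 25, or 15 and 4 adjusted over the list alone (adjusted p = 0.000204). Each of these 4 lists had adjusted p = 0.039 with an estimated correlation. HGF, hepatocyte growth factor, rose by 1.67 ± 0.12 and the Wnt antagonist SFRP4 by 2.15 ± 0.10. Contractile genes fell in 10 and rose in 1 of 19, or 11 and 1 adjusted over the list alone (adjusted p = 4.08e-05; adjusted p = 0.162 with an estimated correlation). Proteases and inhibitors rose in 10 and fell in 1 of 20, or 12 and 1 adjusted over the list alone (adjusted p = 4.53e-05; adjusted p = 0.164 with an estimated correlation), with PLAU, the urokinase gene, at 1.68 ± 0.11. Extracellular matrix genes rose in 12 and fell in 1 of 39, also adjusted over the list alone (adjusted p = 0.000544; adjusted p = 0.422 with an estimated correlation). Endoplasmic reticulum chaperones rose in 9 and fell in 1 of 22, also adjusted over the list alone (adjusted p = 0.000204; adjusted p = 0.0864 with an estimated correlation). Cholesterol genes rose in 7 of 17, or 7 with 1 lower adjusted over the list alone (adjusted p = 0.0205; adjusted p = 0.162 with an estimated correlation), a call that averaging probe sets or a filter at the 60th percentile ended. Amino acid deprivation response genes fell in 11 and rose in 4 of 31, also adjusted over the list alone (adjusted p = 0.0084; adjusted p = 0.245 with an estimated correlation). The TGF-beta, interferon, stromal surface marker and NRF2 lists, called in 5-Aza against DMEM, were not called against alpha MEM (adjusted p = 0.144, 0.144, 0.144 and 0.898). Of the fibroblast markers not yet named, TNC (0.72 ± 0.07), PDGFRB (0.43 ± 0.10) and FAP (0.47 ± 0.06) were higher in 5-Aza than in alpha MEM. ACTA2 (-0.52 ± 0.08), CXCL12 (-0.21 ± 0.07, adjusted p = 0.0442) and DNMT1 (-0.54 ± 0.09) were lower. VIM (-0.03 ± 0.08), FN1 (-0.04 ± 0.08) and THBS1 (0.07 ± 0.09) were not called. As for TCM, the values against alpha MEM include the difference between the control media given above. PDGFRB was not called without MEM replicate 1 (0.30), and the CXCL12 call was lost in 13 of 22 alternatives, among them each 5-Aza array left out (-0.225 to -0.178), MEM replicate 2 (-0.11), and TCM replicate 3, DMEM replicate 1 or DMEM replicate 2 (-0.21 each). The dimmer FN1 probe sets gave -0.35 to 0.31 and the dimmer THBS1 probe sets -0.86 to 0.09. The other TNC probe sets gave 0.127 to 0.451.

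**Figure D3:**
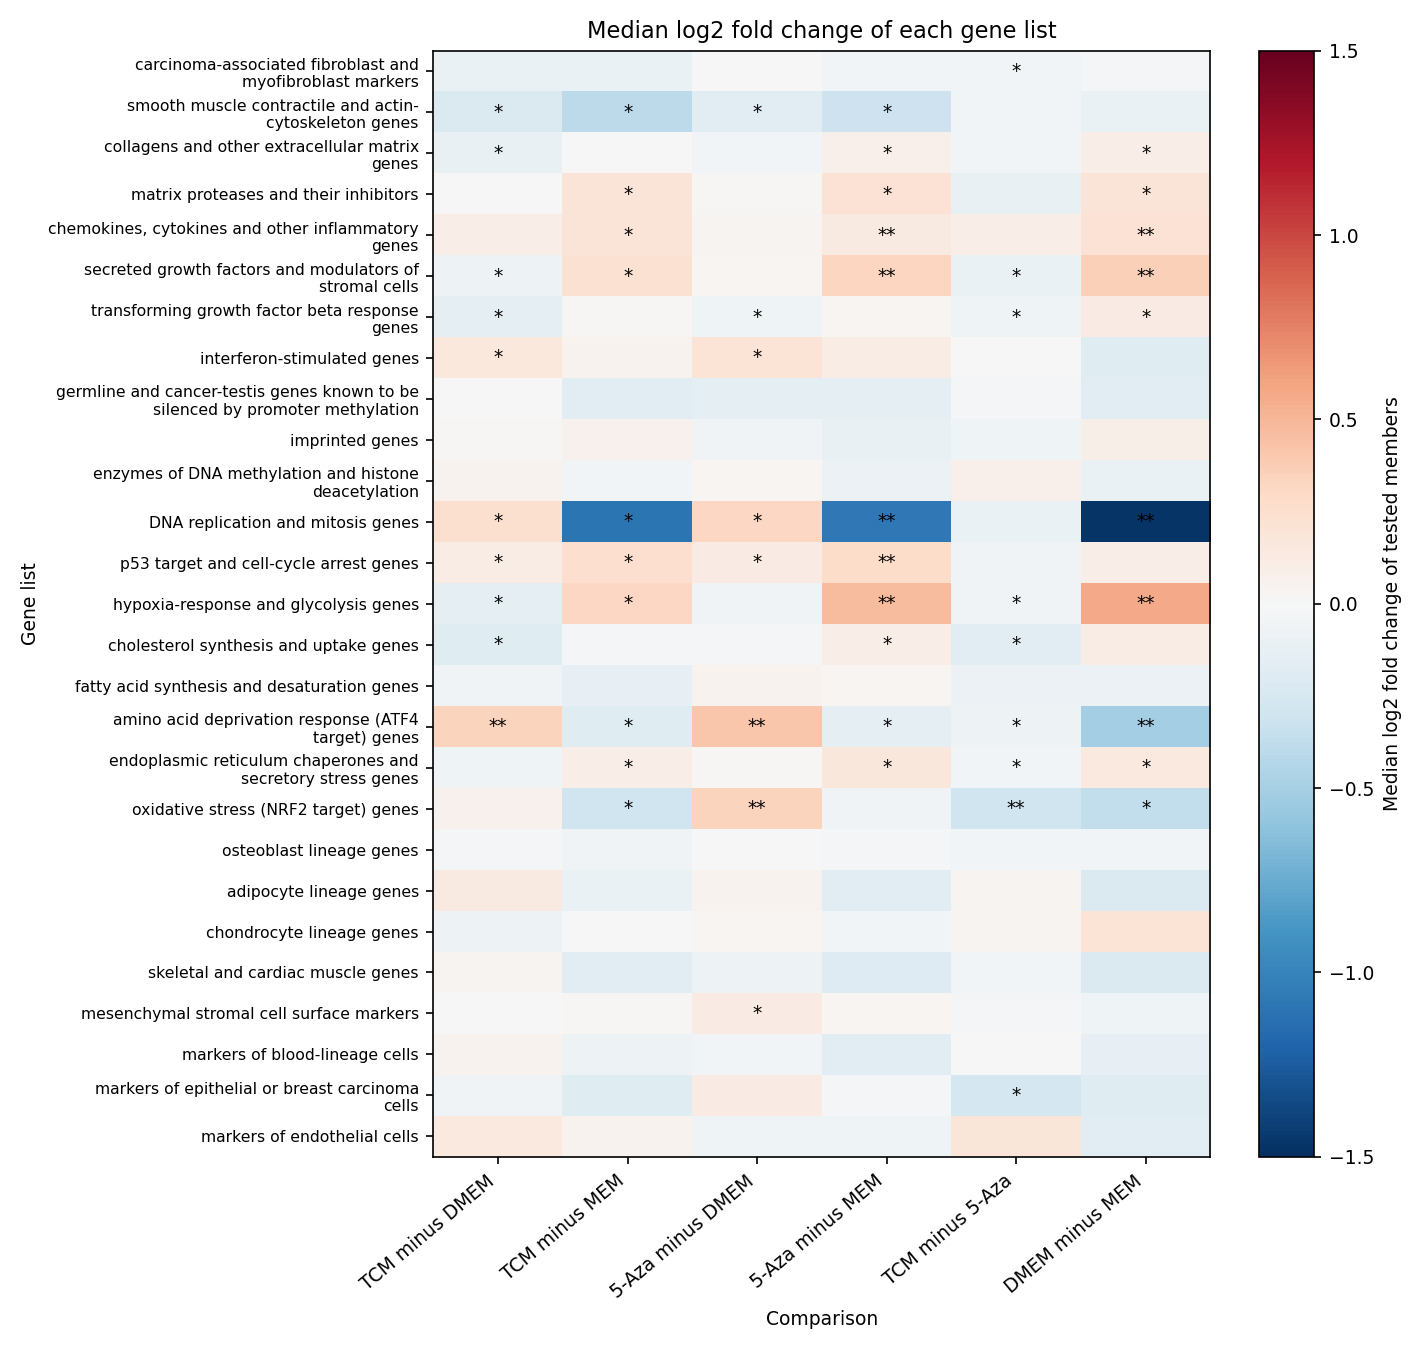
Colour shows the median log2 fold change of the tested members of each of 27 gene lists (vertical) in each of 6 comparisons (horizontal). A single star marks a list called with the preset correlation and a double star one also called with an estimated correlation. The strongest colour is that of DNA replication and mitosis genes in DMEM minus MEM, at -1.47.

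The 2 exposures were then compared directly. Of 16 genes of the NRF2 oxidative stress response 8 were lower in TCM than in 5-Aza, with NQO1 at 642 ± 19.3 and 1286 ± 8.53 (log2 fold change -0.97 ± 0.05, adjusted p = 7.66e-08), although GCLM, a subunit of the glutathione-synthesis enzyme glutamate-cysteine ligase, was higher (0.68 ± 0.06). S100A4 (-0.88 ± 0.10) and CXCL12 (-0.55 ± 0.06) were lower in TCM than in 5-Aza, while COL15A1 (0.57 ± 0.07), VCAM1 (0.79 ± 0.07) and TNC (0.34 ± 0.06) were higher. The second CXCL12 probe set gave 0.02, and with probe sets averaged neither CXCL12 (-0.27) nor TNC (0.22) was called. In total 274 genes were higher and 499 lower, and this count of 773 dropped to 426 without an intensity trend, to 490 when probe sets of a gene were averaged, to 494 without TCM replicate 3 and to 443 without 5-Aza replicate 3.

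The largest increases in TCM over 5-Aza were those of ANO1 (1.43 ± 0.11), the Wnt modulator DKK2 (1.29 ± 0.15, and 0.23 for another probe set), the olfactory receptor gene OR1Q1 (1.17 ± 0.26), the soluble guanylate cyclase subunit GUCY1B1 (1.15 ± 0.14) and the cytokine TNFSF18 (1.15 ± 0.17). The largest decreases were those of the secreted glutathione peroxidase GPX3 (-1.78 ± 0.16), the chloride channel protein CLIC3 (-1.39 ± 0.10), ATF5 (-1.38 ± 0.12), LYPD1 (-1.25 ± 0.18) and THEMIS (-1.24 ± 0.14). The OR1Q1 call was lost without TCM replicate 1 (1.06) or 5-Aza replicate 3 (0.85), with its probe sets averaged (0.63), without the signal filter and without an intensity trend. NRF2 targets were lower in 8 and higher in 1 of 16 members, or 11 and 1 adjusted over the list alone (adjusted p = 5.69e-09; adjusted p = 0.00673 with an estimated correlation). The other 8 called lists were also lower in TCM, and none of them was called with an estimated correlation. These were cholesterol genes (5 of 17 lower; adjusted p = 9.83e-05; adjusted p = 0.0645 with an estimated correlation) and hypoxia and glycolysis genes (5 of 34 lower; adjusted p = 0.000898; adjusted p = 0.407 with an estimated correlation). They were also amino acid deprivation response genes (5 lower and 2 higher of 31; adjusted p = 0.00338; adjusted p = 0.285 with an estimated correlation) and secreted growth factors (5 lower and 3 higher of 34; adjusted p = 0.0293; adjusted p = 0.247 with an estimated correlation). Adjusted over the list alone these 4 lists had 5, 8, 6 and 10 lower and 0, 0, 2 and 5 higher members. Fibroblast markers (5 lower and 1 higher of 19; adjusted p = 0.473 with an estimated correlation), TGF-beta response genes (7 lower and 4 higher of 26; adjusted p = 0.293 with an estimated correlation) and endoplasmic reticulum chaperones (2 of 22 lower; adjusted p = 0.372 with an estimated correlation) each had adjusted p = 0.0415 with the preset correlation. Adjusted over the list alone these 3 lists had 6, 7 and 4 lower and 4, 5 and 0 higher members. The shifts of -0.14, -0.11, -0.10 and -0.08 of the fibroblast marker, growth factor, TGF-beta and chaperone lists were no longer called without TCM replicate 1 (-0.11, -0.084, -0.085 and -0.063) or without 5-Aza replicate 1 (-0.14, -0.11, -0.09 and -0.08). Without 5-Aza replicate 3 the fibroblast marker (-0.12) and chaperone (-0.07) lists were not called, without DMEM replicate 1 the fibroblast marker (-0.14), TGF-beta (-0.10) and chaperone (-0.08) lists, and without DMEM replicate 2 the fibroblast marker list (-0.14). Quantile normalization and a filter at the 60th percentile each ended the calls of these 4 lists, array weights ended all but that of growth factors, and averaging probe sets ended that of the fibroblast markers (-0.095). Quantile normalization also ended the call of the amino acid response list (-0.08). Markers of epithelial or breast carcinoma cells were lower in 4 of 15 members, or 5 adjusted over the list alone (adjusted p = 0.00338; adjusted p = 0.285 with an estimated correlation). The 4 were KRT14 (-0.88 ± 0.09), KRT7 (-0.72 ± 0.10), KRT18 (-0.44 ± 0.09, not called without an intensity trend) and KRT8 (-0.58 ± 0.14), which are all keratins. The KRT8 call was lost without TCM replicate 2 (-0.475) or 3 (-0.59) or 5-Aza replicate 2 (-0.58) or 3 (-0.46). It was also lost without the signal filter and without an intensity trend, and KRT7 gave 0.01 with its probe sets averaged.

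Changes in both exposures were set against separate controls, so that no array entered both sides. Of the genes called in TCM against DMEM and in 5-Aza against alpha MEM, 173 were higher in both, where independent lists would share 85.9, and 159 were lower in both, where 82.6 would be shared. Another 475 genes had opposite directions, where independent lists would give 169.3, so opposite directions exceeded that number by more than shared directions did. The difference between the controls enters both comparisons with opposite signs. A gene with like levels in both exposures that lie between the controls is opposite by construction. The excess of opposite directions and the correlations therefore cannot show that the exposures differ, nor can they with the controls exchanged. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of -0.05 and a Spearman correlation of -0.14. With the controls exchanged, 155 genes were higher in both (90.8 for independent lists), 132 lower in both (69.2) and 492 opposite (159.2).

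Against the shared DMEM control, 360 genes rose in both exposures and 330 fell in both and 18 had opposite directions, where independent lists would give 40, 34.5 and 75.2. Unchanged groups simulated against the same controls shared at most 1 called gene. The simulation held no true change, so few genes could be called at all. It cannot say how many calls unrelated exposures would share through a common control. The Pearson correlation was 0.58 against 0.50 in the simulation, and the covariance 0.0298 against 0.00951. Against the shared alpha MEM control, 1205 genes rose and 1021 fell in both (194.8 and 165.7 for independent lists) with 4 opposite (359.5). The correlation was 0.85 against 0.60 simulated, and the covariance 0.118 against 0.0143. Neither control had enough arrays for 2 on each side of a split, so part of the excess of shared calls may come from the shared controls. With separate arrays of the same control on either side, at least 1 on each, the correlation was 0.222 to 0.359 for DMEM (covariance 0.015 to 0.0217) and 0.646 to 0.66 for alpha MEM (0.101 to 0.103). For each exposure, the directions against the 2 controls also differed in many genes. Of genes called in TCM against both controls, 211 were higher in both (81.0 for independent lists), 256 lower in both (83.9) and 308 opposite (165.1), and for 5-Aza the numbers were 246 (96.3), 163 (68.2) and 376 (162.3). These comparisons share the arrays of the exposure, so independent lists are not their value without change. Simulated unchanged groups shared 0 called genes, which is no measure for groups that did change. The Pearson correlation was 0.227 against 0.448 simulated for TCM (covariance 0.0202 against 0.00955) and 0.137 against 0.447 for 5-Aza (0.0111 against 0.00953).

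Markers of other cell types and lineage genes showed no call for the list as a whole in most comparisons. Blood-lineage markers were not called in any comparison (lowest adjusted p = 0.513), with 1 member higher and 1 lower at most. CD14, a monocyte marker, was at 83.4 ± 13.7 in TCM, 94.3 ± 10.3 in 5-Aza, 97.3 ± 21.7 in DMEM and 3.47 ± 0.23 in alpha MEM. Endothelial markers were not called either (lowest adjusted p = 0.537). Epithelial markers were not called in TCM against DMEM (adjusted p = 0.0997), where 3 of 15 were lower and none higher, or 4 lower adjusted over the list alone, but they were called lower without DMEM replicate 1 (shift -0.16) and with a filter at the 60th percentile (-0.34). Osteoblast (lowest adjusted p = 0.521), adipocyte (0.324), chondrocyte (0.0929), and skeletal and cardiac muscle (0.178) lineage lists were not called in any of the 6 comparisons. Neither were imprinted genes (0.199), germline genes (0.703), enzymes of DNA methylation and histone deacetylation (0.106), or fatty acid synthesis genes (0.0635). Single members did change. In TCM against DMEM, the transcription factor genes CEBPD and SOX9 fell by 0.75 ± 0.07 and 0.44 ± 0.08 on the log2 scale, ALPL, alkaline phosphatase, rose by 0.61 ± 0.11 and SPP1, osteopontin, by 0.52 ± 0.12 (0.28 and not called with its probe sets averaged). Among imprinted genes PLAGL1 fell in both exposures against DMEM (-0.62 ± 0.06 in TCM and -0.29 ± 0.06 in 5-Aza). In 33 of the 162 pairs of list and comparison the median, the mean and the test differed in sign, and none of these pairs was called.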

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

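The fit without the MEM group and the count of shared genes without an intensity trend were chosen after the data were seen. The former gave 1442 genes in TCM against DMEM, 1363 in 5-Aza against DMEM and 747 in TCM against 5-Aza. The counts of called genes in the 6 comparisons, the 58 called pairs of list and comparison (53 to 65 over the alternatives) and the 332 genes shared without a common control (238 without an intensity trend to 388 with quantile normalization) stayed within 1.5 times their value, with these exceptions. Without an intensity trend 983, 947 and 426 genes were called in TCM against DMEM, 5-Aza against DMEM and TCM against 5-Aza, and averaging probe sets gave 490 in the last. Leaving out 1 array gave 2065 (MEM replicate 2) to 3251 genes in 5-Aza against MEM, with 2144 without MEM replicate 1, and 443 (5-Aza replicate 3) to 785 in TCM against 5-Aza, with 494 without TCM replicate 3. Each such fit has fewer arrays; the cause of the other shifts was not tested. For the named genes 4020 values kept direction and side of the threshold, 51 lost the call, 3 gained it and 38 changed direction, and for the lists 1275, 38, 3 and 6. No value could be had for 2 gene values and 1 list value under the filter at the 60th percentile.

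The direction of a list above is that of its test. KRT7 in TCM against 5-Aza was the single called gene whose direction turned (0.005 with probe sets averaged). The shift of the extracellular matrix list, called in TCM against DMEM, turned to 0.011 with quantile normalization, where the call was lost and the test kept its direction. The other turns concerned genes and lists that were not called, including the shift of the germline list in 5-Aza against DMEM without a filter (0.008). With quantile normalization DNMT1 was at -0.006 in 5-Aza against DMEM, VIM at 0.03 in 5-Aza against MEM, 0.058 in TCM against DMEM and 0.06 in TCM against MEM, and THBS1 at 0.05 in TCM against DMEM. With centring, DNMT1, THBS1 and VIM were at -0.025, -0.019 and -0.018 in 5-Aza against DMEM and VIM at 0.014 in 5-Aza against MEM. With the larger pseudocount DNMT1 was at 0, and with array weights THBS1 and VIM were at -0.013 and -0.009, all in 5-Aza against DMEM. With probe sets averaged THBS1 was at -0.336 in 5-Aza against DMEM, -0.211 in 5-Aza against MEM and -0.155 in TCM against MEM, and VIM at 0.038 in 5-Aza against MEM and 0.175 in TCM against DMEM. The direction of the test of the fibroblast marker list in 5-Aza against DMEM turned with the filter at the 60th percentile (shift 0.026) and with probe sets averaged (0.02). The cause was not tested.

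With 1 array left out, in 5-Aza against DMEM the fibroblast marker list ranged from 0.003 to 0.067, the germline list from -0.116 to 0.033, DNMT1 from -0.041 to 0.051, FN1 from -0.104 to 0.032, THBS1 from -0.095 to 0.058 and VIM from -0.053 to 0.086. In 5-Aza against MEM, FN1 ranged from -0.132 to 0.043, THBS1 from -0.03 to 0.123 and VIM from -0.086 to 0.054. In TCM against DMEM, THBS1 ranged from -0.062 to 0.011 and VIM from -0.068 to 0.006, and in TCM against MEM THBS1 ranged from -0.02 to 0.078.

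The replicate numbers did not pair the arrays. Deviations of the 15 pairs of arrays with the same number had correlations of -0.159 to 0.018, 0 of them above 0.1, and 0 of 11 arrays correlated best with their own number. With the number as a replicate block 1266, 2793, 1203, 2815, 654 and 3543 genes were called in TCM against DMEM, TCM against MEM, 5-Aza against DMEM, 5-Aza against MEM, TCM against 5-Aza and DMEM against MEM, with 59 list pairs and 279 shared genes. Among named genes and lists the block ended the call of CXCL12 in 5-Aza against MEM (-0.202) and changed no other call. Signals near the filter of 22.9 limit what could be seen of genes with low expression.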

Other observations

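The comparisons of marker genes with all genes, and of lists with their nearest neighbours in signal, were tests chosen after the results were seen.

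Other splits of the arrays into 3 and 3 were counted for the comparisons between groups of 3. In TCM against DMEM 1 of the 10 splits, the real one with 1485 genes, gave as many called genes, and the highest other split gave 0. For 5-Aza against DMEM this was 1 of 10 (1437 genes, highest other 1), and for TCM against 5-Aza 1 of 10 (773 genes, highest other 1). With 10 splits a share under 0.05 cannot be reached.

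Genes of DNA replication and mitosis were lower in DMEM than in alpha MEM, at a median log2 fold change of -1.466. An array effect that depends on signal level is argued against by 10000 random lists of matched signal, whose lowest median was -0.303 (-0.318 for lists drawn from the 50 nearest genes in signal). Blood-lineage or endothelial cells in the MEM cultures left no sign in their 20 tested markers, of which 0% were called higher in MEM, against 14.3% of all genes. Another 8 blood-lineage and 7 endothelial markers were below the signal filter. A marker high on the MEM arrays alone could fail that filter, so such cells cannot be excluded. Epithelial cells stay open, with 20% of 15 tested markers called higher in MEM, 2 called lower in MEM and another 13 markers below the signal filter. The medium, and a difference in passage, density or donor, stay open and untested.

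Amino acid response genes were higher in TCM than in DMEM, at a median of 0.335, above the highest of 10000 lists of matched signal at 0.14 (0.127 with nearest neighbours). A single aberrant DMEM array is argued against, because at least 20 members were called higher whichever DMEM array was left out. The list was also higher in 5-Aza than in DMEM and lower in DMEM than in alpha MEM, and in TCM against alpha MEM 13 of 31 members were lower and 2 higher (adjusted p = 9.40e-05; adjusted p = 0.101 with an estimated correlation). TCM cells were thus above DMEM cells and not above alpha MEM cells, so both the conditioned medium and a low level in the DMEM cultures stay open and untested.

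Of 19 contractile genes 9 were called lower than in DMEM in TCM and 7 in 5-Aza, and the calls of the list were lost with an estimated correlation (adjusted p = 0.064 and adjusted p = 0.145 with an estimated correlation). Their medians of -0.215 and -0.169 lay beyond the lowest of 10000 lists of matched signal at -0.197 and -0.146, but by small margins. Lists of nearest neighbours in signal reached -0.184 and -0.123, while 6 of the 19 members are among the 200 genes of highest signal, whose median was -0.079 in TCM against DMEM and -0.023 in 5-Aza against DMEM. At least 6 members were called lower in TCM whichever of the 6 arrays was left out, which argues against a single aberrant array. The exposures stay open as an explanation and were not tested further, and the days of culture differed for 5-Aza.

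The hypothesis that exposed cells lie between both control media was tested on genes that differed between DMEM and alpha MEM by a log2 change of more than 1, with separate DMEM arrays for both distances. The median fraction of the way from DMEM to alpha MEM was 0.104 to 0.161 in TCM over 3 rotations of the DMEM arrays (419 to 482 genes, 64.7% to 72.2% of them with a positive fraction) and 0.146 to 0.197 in 5-Aza (72.6% to 77.3%). All values lay above the bound of 0.1 set beforehand, in TCM by a small margin, so the hypothesis may hold for a small part of the distance.

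If 5-azacytidine had opened genes silenced by DNA methylation, more genes of low signal should have risen in 5-Aza than in TCM. Of 4659 genes at or below the signal filter in both control groups, 16 were called higher and 11 lower in 5-Aza against DMEM, compared with 24 higher and 5 lower in TCM against DMEM. Against alpha MEM 28 were higher and 47 lower in 5-Aza, and 32 and 37 in TCM. These data do not show the predicted excess at the time sampled, and changes below the background of the arrays cannot be excluded. The dose and length of exposure are not given, which limits what the absence of an excess can mean.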
